A study of Macaca mulatta with 52 samples.

How the data were processed

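Bulk RNA of DLPFC, ACC, HC and V1 from 13 rhesus macaques, female per the labels, was sequenced as ribosomal-RNA-depleted, stranded libraries, 1 per animal and region. Per the labels, libraries were pooled by 24, sequenced in 2 batches with paired 69 bp reads to a mean of about 50 M reads, M standing for 1000000. Per the submitters' processing notes, the tools named were STAR, kallisto, Picard, edgeR, limma and R 3.6.0 with the rheMac8 build; their roles and order are not given in the sources used here. Expression values per library were not used here, so no gene was refitted.

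The authors' deposited comparison table gives a log fold change, read here as log2, with a p-value and an FDR of 14975 genes for 4 regions and their combination. Per the file headers, neither the groups, the direction nor the base of the logarithm is stated; MIA of both trimesters over control on the log2 scale is the reading used throughout. The direction follows the usual order of case over control and was not settled by any value in the table. The p-values and FDR are the authors'. The FDR of the 4 regions rises with p as 1 shared function, and the method behind it is not given in the sources used here. Whether the authors' fit adjusted for batch or for measures of RNA quality is not known here. The authors' deposited module table gives each gene's module and its module membership score (kME). The authors' deposited metadata give per library the sequencing depth, the sequencing batch, the RNA integrity number as a score, both usual absorbance ratios of RNA purity, and 4 scores named seqPC1 to seqPC4 whose making is not stated. Rows of the metadata were matched to animals and regions by the sample names.

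Genes were named by the files and, by gene ID, by a reference table that gave 12271 of the 14975 identifiers a symbol. A row belonged to a list where either name matched, and 46 of 767 list memberships rested on the reference symbol alone. Entries that share a name count once each, so the ribosomal list has 73 genes and 77 measured entries with 47 names of the file; an alternative kept 1 entry per name. The reference assembly differs from rheMac8, so no coordinates are given.

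Groups came from the labels. Choices made before the data were examined were the lists, the tests, the threshold of 0.05 and the rule for named genes. Called genes are those with a deposited FDR under 0.05. The rule named the 3 genes with the smallest p in each direction per region among called genes with a symbol, 6 per direction for the combined comparison, up to 10 genes called in the most regions, up to 4 members per list and comparison, and 3 hub genes per module. Some genes that the rule takes are not reported here. FAT2, GABRA6, CBLN3 and MBP fall outside the rule and were named after their values were seen, and the cerebellum list was written after the V1 calls were seen.

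Gene lists of cell types, synapses, immunity, retrotransposons, stress, metabolism and autism risk were tested with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, on the normal quantile of the deposited p with the sign of the fold change. The inter-gene correlation was preset to 0.01, lists of fewer than 5 measured members were left out, which left 34 of 35, and Benjamini-Hochberg adjustment ran over 34 lists and 5 comparisons. An estimated correlation was built from the deposited module memberships of each list's members and of 20 hub genes per module. It approximates a correlation that values per library would give, and differences between regions are included in it as far as they entered the modules. On simulated data of 14975 genes, 2.97% of unchanged lists had p under 0.05, 94% of lists of 25 shifted by 1 were called, and 22% of unchanged lists of 25 with a correlation of 0.1 had p under 0.05. The estimated correlations ran from 0 for the glucocorticoid response list to 0.913 for the myelin list, with 0.210 for ribosomal proteins. Lists above 0.1 lie beyond what was simulated, so 22% is not their false positive rate. Medians were placed among 10000 random lists of the same size, unmatched because the table gives no mean expression. The alternatives tried were other thresholds and adjustments, other correlations and statistics for the lists, module members of high membership, Spearman's rho and metadata without each animal. Lists were compared between regions with cameraPR on the difference of deposited log2 fold changes, over 204 tests. This difference was not scaled by each gene's error, so genes with large but uncertain fold changes weigh more. No p is given for the lists of cerebellar genes, which were added later.

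Modules were tested against lists with Fisher's exact test, two-sided, over 986 tests. Metadata were compared with exact permutation tests, two-sided as 2 times the smaller tail, over animal means, with Benjamini-Hochberg adjustment over 24 tests; 5 against 4 animals can reach p = 0.0159. Batch by exposure was tested with Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Depth sets the precision of each value, but the deposited comparison table carries no error, so none is printed beside its fold changes.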

Results

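RNA sequencing profiled 4 brain regions of 13 rhesus macaques that differed in their exposure to maternal immune activation (MIA) during gestation. MIA was induced in pregnancy with poly:ICLC, a synthetic double-stranded RNA that imitates a viral infection. The dose was 0.25 mg/kg, given on days 43, 44 and 46 of gestation for first-trimester MIA (n = 5) and on days 100, 101 and 103 for second-trimester MIA (n = 4). The control group (n = 4) held 1 untreated animal, 1 animal of a first-trimester saline injection and 2 of second-trimester saline injections. Brain tissue was collected when the animals were between 3.5 and 4 years old. It came from dorsolateral prefrontal cortex (DLPFC), anterior cingulate cortex (ACC), hippocampus (HC) and primary visual cortex (V1), which gave 52 libraries. The comparisons ask how expression in the brain of these animals differed after MIA.

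The deposited metadata listed a sequencing depth of 29.0 ± 7.21 M (SD, n = 52 libraries), from 15.7 to 54.2 M, where M stands for 1000000 of the deposited unit. The labels state a mean of about 50 M reads. Mean depth was 34.6 ± 11.1 M in DLPFC, 29.2 ± 2.42 in ACC, 28.6 ± 2.61 in HC and 23.7 ± 4.54 in V1 (SD, n = 13 libraries each). DLPFC was split over both sequencing batches, with 9 libraries in the first and 4 in the second, and all libraries of the other regions lay in the second batch. In DLPFC the first batch held 7 of 9 MIA and 2 of 4 control libraries, and its mean depth was 28.1 ± 4.77 M against 49.1 ± 4.76 in the second (exact permutation test, two-sided, p = 0.00280). The RNA integrity number ran from 3.9 in 1 second-trimester HC library to 8.8, and 5 of 16 control and 2 of 36 MIA libraries lay under 7.

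**Figure D1:**
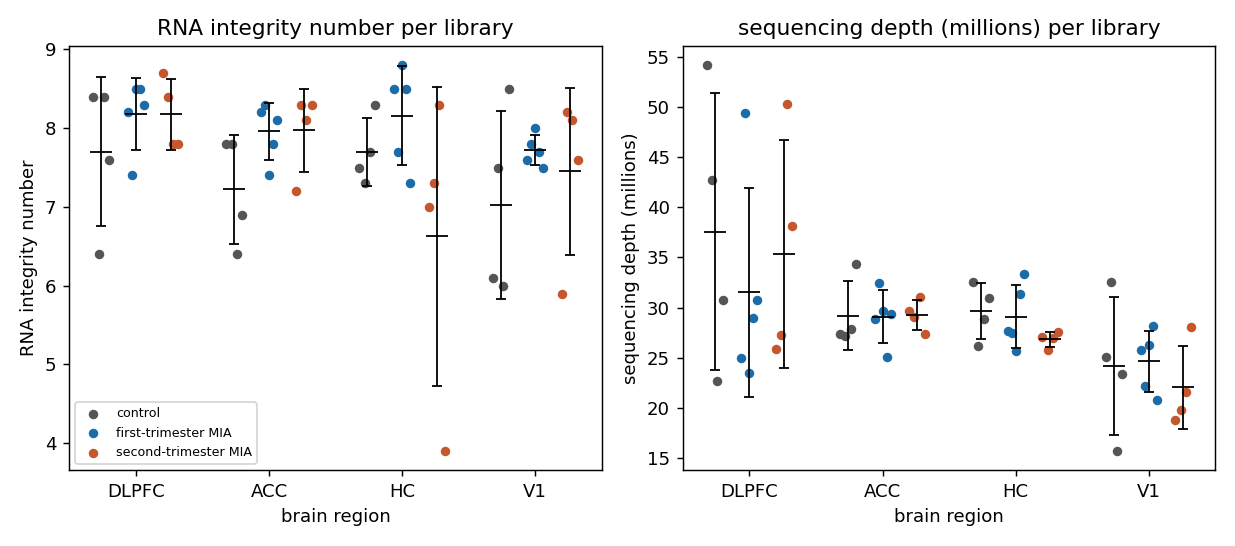
RNA integrity number (left) and sequencing depth in M (right) of each of the 52 libraries, by brain region and exposure. Points are libraries and black bars are the mean ± SD; the lowest integrity, 3.9, is a second-trimester HC library and the lowest depth, 15.7 M, a control V1 library.

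Per animal, averaged over regions, the RNA integrity number was 8.01 ± 0.188 after first-trimester MIA (SD, n = 5), 7.56 ± 0.597 after second-trimester MIA (SD, n = 4) and 7.41 ± 0.306 in controls (SD, n = 4). Exact permutation tests, two-sided, gave p = 0.0476 for first-trimester MIA against control and p = 0.771 for second-trimester MIA against control. The absorbance ratio that falls with salt or solvent carryover was 1.99 ± 0.024 after first-trimester MIA and 2.12 ± 0.063 in controls (exact permutation test, two-sided, p = 0.0159). For pooled MIA, the comparison that the fold changes use, it was 2.02 ± 0.0598 (SD, n = 9; exact permutation test against control, two-sided, p = 0.0392, adjusted p = 0.313 over the pooled tests). In DLPFC alone it was 1.99 ± 0.244 after pooled MIA, 1.85 ± 0.154 after first-trimester MIA and 2.19 ± 0.0981 in control (exact permutation tests against control, two-sided, p = 0.157 and 0.0317, adjusted p = 0.812 and 0.994). Over the 24 such tests of 8 measures between the 3 exposures, 3 unadjusted p lay under 0.05 and no Benjamini-Hochberg adjusted p did. A single test at the smallest p that 5 against 4 animals allow cannot pass this adjustment. The smallest adjusted p was 0.381. Within the DLPFC batches the integrity number was 8.34 in 7 MIA and 8.0 in 2 control libraries of the first batch (exact permutation p = 0.333). It was 7.60 in 2 MIA and 7.40 in 2 control libraries of the second. Neither batch can pass 0.05, since the smallest exact p is 0.0556 for 7 against 2 libraries and 0.333 for 2 against 2.

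The authors' deposited table lists a log fold change, a p-value and a false discovery rate (FDR) of 14975 genes for each region and for the 4 regions combined. Its header names neither the groups nor their order nor the base of the logarithm; the values were read as log2 of MIA, both trimesters pooled, over control. With that reading, the authors' deposited table had an FDR under 0.05 for 14 genes in DLPFC, 7 higher and 7 lower, and for 1 lower gene in ACC. In HC 47 genes passed in the authors' deposited table, 26 higher and 21 lower, and in V1 73, 6 higher and 67 lower. The combined comparison of the authors' deposited table passed 1 higher and 2 lower genes. The share of genes with a positive value was 53.1% in DLPFC, 49.6% in ACC, 50.0% in HC and 50.4% in V1. The FDR of the 4 regions was 1 shared increasing function of p. Benjamini-Hochberg adjustment within each comparison instead left 0 genes in DLPFC and ACC, where 772 and 202 genes had an unadjusted p under 0.05. It left 3 genes each in HC, V1 and the combined comparison. First- and second-trimester effects on genes were not analysed here, because the table holds 1 comparison per region.

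PIWIL2, a PIWI protein that silences transposons in the germ line, was called lower in 3 regions, more than any other gene. The authors' deposited table gave PIWIL2 (ENSMMUG00000014438) a log2 fold change of -2.04 in DLPFC (FDR = 0.00134), -1.39 in ACC (FDR = 0.0196) and -1.33 in HC (FDR = 0.0195). The regions came from the same 13 animals, so these 3 calls are not independent of each other. In V1 the authors' deposited table gave PIWIL2 -0.39, which did not pass (FDR = 0.859), and whether V1 differed from the other regions was not tested. C15orf41 (ENSMMUG00000006837), a nuclease gene mutated in congenital dyserythropoietic anaemia, was higher in DLPFC (1.02, FDR = 0.0108) and HC (0.87, FDR = 0.0122) in the authors' deposited table. MGARP (ENSMMUG00000004196), which encodes a mitochondrial protein, was lower in DLPFC (-1.33, FDR = 0.0128), and ACC stood at -0.95 without passing (FDR = 0.0593) in the authors' deposited table. These were the 3 genes of the combined comparison of the authors' deposited table, with PIWIL2 at -1.29 (FDR = 4.24e-06), MGARP at -0.83 (FDR = 0.00273) and C15orf41 at 0.63 (FDR = 0.00357). The deposited FDR of PIWIL2 lies well below what Benjamini-Hochberg adjustment of its deposited p, 8.18e-08, over all genes would give. Of the 132 genes called in at least 1 region, 130 were called in 1 region, 1 in 2 and 1 in 3, and none in opposite directions.

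**Figure D2:**
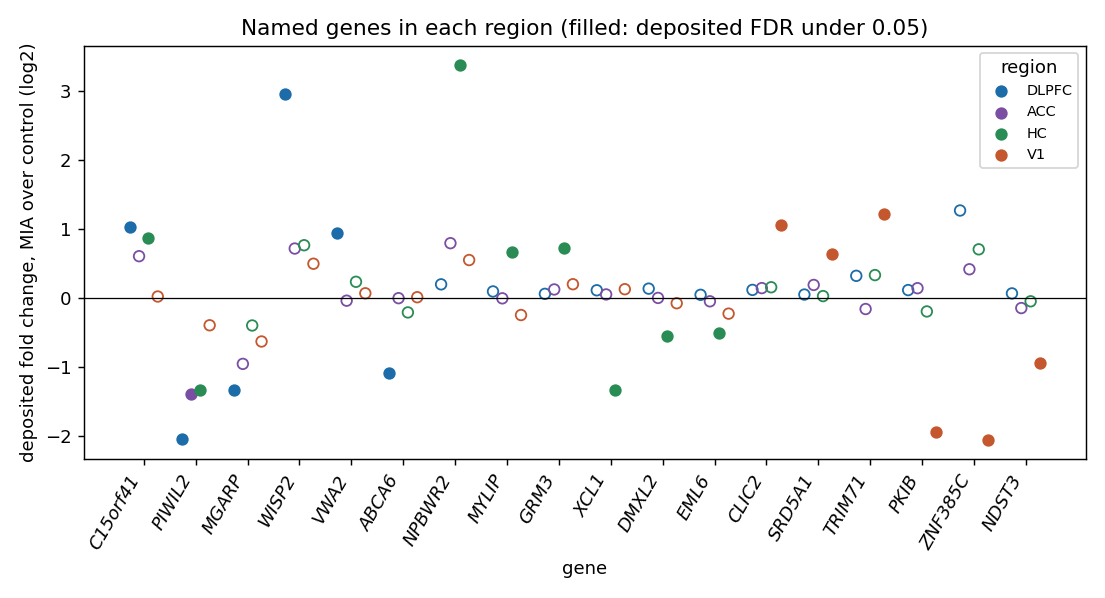
Log2 fold change of each named gene, MIA over control, in the 4 regions, from the authors' deposited table. Filled points have a deposited FDR under 0.05 and open points do not; PIWIL2 is filled and below 0 in DLPFC, ACC and HC, with no error bars because the table gives none.

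In DLPFC, genes for ribosomal proteins and for the respiratory chain lay lower, and vascular, astrocyte, glutamate receptor and autism risk genes higher. Among single genes, the authors' deposited table listed WISP2, a secreted matricellular protein, at 2.96 (FDR = 0.00712) and VWA2, an extracellular matrix gene, at 0.94 (FDR = 0.0285). ABCA6, of a family of lipid transporters, stood at -1.08 (FDR = 0.0199) in the authors' deposited table. Gene lists were tested with cameraPR (limma) at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 170 tests. Members were counted as entries of the table, and some share a gene name or matched by the reference symbol. Of the ribosomal protein genes, 70 of 77 measured members were lower, with a median of -0.21 (adjusted p = 1.31e-18; adjusted p = 0.426 with an estimated correlation). With 1 entry per gene name, 42 of 47 were lower, with a median of -0.21 (adjusted p = 8.73e-14). Examples from the authors' deposited table were RPL18 (-0.60), RPL26 (-0.79), RPL23 (-0.41) and RPS9 (-0.44). Of the nuclear-encoded oxidative phosphorylation genes, 48 of 55 measured members were lower, with a median of -0.17 (adjusted p = 7.76e-09; adjusted p = 0.570 with an estimated correlation). They included NDUFA4 (-0.34), COX4I1 (-0.48) and NDUFB6 (-0.37) in the authors' deposited table, where ATP5B went the other way at 1.53. The 13 genes encoded by mitochondrial DNA had a median of 0.02 (adjusted p = 0.985). Of the pericyte and smooth muscle genes, 11 of 11 measured members were higher, with a median of 0.43 (adjusted p = 0.000820; adjusted p = 0.651 with an estimated correlation), with RGS5 (0.56), NOTCH3 (0.87) and PDGFRB (0.43) in the authors' deposited table. Of the endothelial genes, 11 of 13 measured members were higher, with a median of 0.30 (adjusted p = 0.00145; adjusted p = 0.651 with an estimated correlation). Of the astrocyte genes, 13 of 15 measured members were higher, with a median of 0.18 (adjusted p = 0.00136; adjusted p = 0.570 with an estimated correlation), with GJA1 (0.35), GLUL (0.28) and AGT (0.57) in the authors' deposited table. Of the ionotropic glutamate receptor genes, 17 of 18 measured members were higher, with a median of 0.16 (adjusted p = 0.00832; adjusted p = 0.821 with an estimated correlation). Among the postsynaptic density genes, 26 of 29 measured members were higher, with a median of 0.12 (adjusted p = 0.0174; adjusted p = 0.870 with an estimated correlation). Of the high-confidence autism risk genes, 31 of 37 measured members were higher, with a median of 0.13 (adjusted p = 0.000848; adjusted p = 0.821 with an estimated correlation). Of the myelin genes, 24 of 25 measured members were lower, with a median of -0.20 (adjusted p = 0.0352; adjusted p = 0.969 with an estimated correlation). Among the microglia genes, 15 of 19 measured members were lower, with a median of -0.12 (adjusted p = 0.0381; adjusted p = 0.870 with an estimated correlation); the call ended with 1 entry per gene name (adjusted p = 0.0509). Adjusted over the list alone, 2 pericyte and smooth muscle genes passed and no member of the other 9 lists did. Over all genes, no member of the 10 lists had a deposited FDR under 0.05. DLPFC was the region split by sequencing batch, and its solvent-carryover absorbance ratio was lower after first-trimester MIA than in control. Its RNA integrity number was 8.18 ± 0.424 after pooled MIA (SD, n = 9) and 7.70 ± 0.945 in control (SD, n = 4), where the lowest library stood at 6.4. Whether the deposited fold changes were adjusted for any of these is not known here. Values per library would be needed to separate any of these from MIA.

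In ACC, PIWIL2 was the 1 gene called, and respiratory chain and cholesterol synthesis genes lay slightly higher. The SD of log2 fold changes over genes was 0.167, the smallest of the 4 regions. FOSB, an immediate early transcription factor, had -0.62 in the authors' deposited table and did not pass (FDR = 0.427). Of the oxidative phosphorylation genes, 46 of 55 measured members were higher, with a median of 0.06 (adjusted p = 0.000357; adjusted p = 0.729 with an estimated correlation). Of the cholesterol and lipid synthesis genes, 21 of 25 measured members were higher, with a median of 0.07 (adjusted p = 0.00518; adjusted p = 0.870 with an estimated correlation), with NSDHL (0.21), MVD (0.24) and MSMO1 (0.20) in the authors' deposited table. Of the myelin genes, 23 of 25 measured members were higher, with a median of 0.17 (adjusted p = 0.0352; adjusted p = 0.969 with an estimated correlation). Among the ribosomal protein genes, 56 of 77 measured members were higher, with a median of 0.03 (adjusted p = 0.0352; adjusted p = 0.910 with an estimated correlation); the call ended with 1 entry per gene name (adjusted p = 0.237). Of the autism risk genes, 25 of 37 measured members were lower, with a median of -0.05 (adjusted p = 0.0203; adjusted p = 0.870 with an estimated correlation), with KMT2C (-0.26) and ADNP (-0.13) in the authors' deposited table. Over all genes and adjusted over the list alone, no member of these 5 lists passed. None of the 5 calls held at a preset correlation of 0.05.

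In HC, myelin genes were higher as a group and synaptic vesicle genes lower. The authors' deposited table placed NPBWR2, a receptor for neuropeptides B and W, at 3.38 (FDR = 0.000234), MYLIP, a ubiquitin ligase for lipoprotein receptors, at 0.67 (FDR = 0.000234) and GRM3, a metabotropic glutamate receptor, at 0.72 (FDR = 0.00297). The genes that fell with the smallest p in the authors' deposited table were XCL1, a lymphocyte chemokine (-1.33, FDR = 0.000842), DMXL2, a protein of synaptic vesicles (-0.54, FDR = 0.00145), and EML6, a microtubule-associated protein (-0.50, FDR = 0.0149). Of the myelin and mature oligodendrocyte genes, 25 of 25 measured members were higher, with a median of 0.81 (adjusted p = 9.28e-16; adjusted p = 0.651 with an estimated correlation). Over all genes no myelin gene passed, and adjusted over the list alone 21 of 25 did, with MYRF (0.99), PLLP (0.81), CNDP1 (0.81) and OLIG2 (0.46) in the authors' deposited table. Beside them, 9 of 9 choroid plexus and ependyma genes were higher with a median of 0.75 (adjusted p = 0.0970). Of the meninges and fibroblast genes, 9 of 10 measured members were higher, with a median of 0.56 (adjusted p = 0.0292; adjusted p = 0.870 with an estimated correlation). Of the endothelial genes, 12 of 13 measured members were higher, with a median of 0.28 (adjusted p = 0.00145; adjusted p = 0.651 with an estimated correlation). Among the pericyte and smooth muscle genes, 11 of 11 measured members were higher, with a median of 0.33 (adjusted p = 0.0338; adjusted p = 0.870 with an estimated correlation). Of the reactive astrocyte genes, 12 of 12 measured members were higher, with a median of 0.27 (adjusted p = 0.0216; adjusted p = 0.821 with an estimated correlation). Among the perineuronal net and extracellular matrix genes, 14 of 20 measured members were higher, with a median of 0.25 (adjusted p = 0.0352; adjusted p = 0.570 with an estimated correlation); the call ended with 1 entry per gene name (adjusted p = 0.0726). Of the interferon-stimulated and antiviral genes, 28 of 36 measured members were higher, with a median of 0.16 (adjusted p = 0.00832; adjusted p = 0.870 with an estimated correlation), with IRF9 (0.40), IRF7 (0.70), IFIH1 (0.44) and IFITM3 (0.42) in the authors' deposited table. Of the synaptic vesicle and presynaptic genes, 23 of 28 measured members were lower, with a median of -0.19 (adjusted p = 0.00215; adjusted p = 0.870 with an estimated correlation), with PPFIA2 (-0.62), RIMS1 (-0.38), PCLO (-0.38) and SYN2 (-0.52) in the authors' deposited table. Of the ionotropic glutamate receptor genes, 15 of 18 measured members were lower, with a median of -0.16 (adjusted p = 0.0203; adjusted p = 0.870 with an estimated correlation). Among the autism risk genes, 30 of 37 measured members were lower, with a median of -0.10 (adjusted p = 0.0203; adjusted p = 0.870 with an estimated correlation). Adjusted over the list alone and over all genes, no member of the 9 lists other than myelin passed. An HC library of second-trimester MIA had the lowest RNA integrity number, 3.9.

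In V1, genes characteristic of cerebellar neurons were lower, and 67 of the 73 genes called in the authors' deposited table were lower. By smallest p, the authors' deposited table listed PKIB, an inhibitor of protein kinase A (-1.93, FDR = 0.000216), ZNF385C, a zinc finger gene (-2.05, FDR = 0.000230), and NDST3, an enzyme of heparan sulfate synthesis (-0.94, FDR = 0.000974). The genes that rose in the authors' deposited table included CLIC2, an intracellular chloride channel gene (1.06, FDR = 0.0123), SRD5A1, a steroid reductase (0.64, FDR = 0.0126), and TRIM71, an RNA-binding protein (1.21, FDR = 0.0198). A list of 43 cerebellar genes was written after these calls had been seen, so its direction in V1 is not independent evidence. On this list, 31 of 33 measured members were lower, with a median of -1.01, and no p is given for it. Over all genes 10 members had a deposited FDR under 0.05, and none passed with Benjamini-Hochberg adjustment within V1. Among them the authors' deposited table had CBLN1 at -3.17, FAT2 at -3.84 and CALB1 at -1.46, all with an FDR under 0.05. The same list had medians of 0.07 in DLPFC, -0.02 in ACC and 0.07 in HC. It held 10 of the 67 lower genes, and 63 called genes remained without it. The calbindin and calretinin genes CALB1 and CALB2, on the inhibitory interneuron list, passed in V1 at -1.46 and -1.40 in the authors' deposited table, while 16 of that list's 20 members were higher (adjusted p = 0.526). Of the oxidative phosphorylation genes, 49 of 55 measured members were higher, with a median of 0.14 (adjusted p = 1.42e-07; adjusted p = 0.570 with an estimated correlation), with ATP5G1 (0.40), NDUFB6 (0.42) and NDUFA4 (0.33) in the authors' deposited table. Of the ribosomal protein genes, 58 of 77 measured members were higher, with a median of 0.07 (adjusted p = 0.00755; adjusted p = 0.879 with an estimated correlation). Among the myelin genes, 25 of 25 measured members were higher, with a median of 0.25 (adjusted p = 0.0113; adjusted p = 0.966 with an estimated correlation). Of the dopamine, serotonin and neuropeptide genes, 20 of 25 measured members were higher, with a median of 0.20 (adjusted p = 0.0203; adjusted p = 0.870 with an estimated correlation). Of the autism risk genes, 28 of 37 measured members were lower, with a median of -0.12 (adjusted p = 0.0113; adjusted p = 0.870 with an estimated correlation), with CHD8 (-0.24), KMT5B (-0.28), TCF20 (-0.19) and SCN2A (-0.26) in the authors' deposited table. No member of these 5 lists passed over all genes or adjusted over the list alone. A control V1 library had the lowest sequencing depth of all 52, 15.7 M, with an RNA integrity number of 6.0. The lowest integrity number in V1 was 5.9, in a library of second-trimester MIA with a depth of 18.8 M.

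In the combined comparison, 4 of the lists fixed beforehand were called, all higher. Of the myelin genes, 25 of 25 measured members were higher, with a median of 0.24 (adjusted p = 4.95e-06; adjusted p = 0.870 with an estimated correlation). Among the endothelial genes, 12 of 13 measured members were higher, with a median of 0.13 (adjusted p = 0.000105; adjusted p = 0.570 with an estimated correlation). Of the pericyte and smooth muscle genes, 10 of 11 measured members were higher, with a median of 0.18 (adjusted p = 0.00757; adjusted p = 0.748 with an estimated correlation). Among the interferon-stimulated genes, 26 of 36 measured members were higher, with a median of 0.07 (adjusted p = 0.0180; adjusted p = 0.870 with an estimated correlation). The combined log2 fold change equals the mean of the 4 regions in the authors' deposited table, so these values repeat those of the regions. The added cerebellum list, written after the V1 calls, had 28 of 33 measured members lower, with a median of -0.24 in the combined comparison. No member of the 4 lists passed over all genes or adjusted over the list alone. Over the 5 comparisons, 34 list calls were made at the preset correlation of 0.01. None of them held with a correlation estimated from the deposited module memberships.

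**Figure D3:**
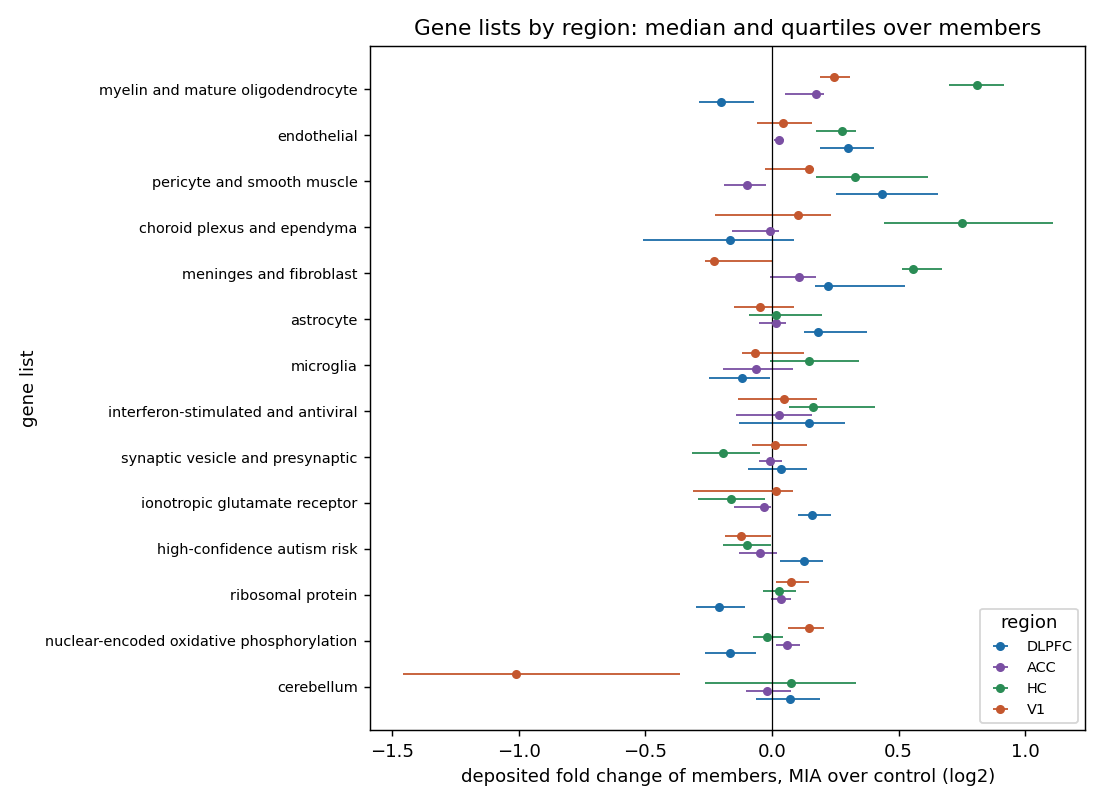
Median deposited log2 fold change, MIA over control, of 14 gene lists in the 4 regions, with bars from the lower to the upper quartile over members. The myelin median is 0.81 in HC and -0.20 in DLPFC, and the cerebellum median is -1.01 in V1.

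Effects in the 4 regions were weakly related across genes. Pearson's r of the deposited log2 fold changes over 14975 genes was 0.26 for DLPFC and ACC, 0.17 for DLPFC and HC and 0.27 for ACC and HC. It was 0.19 for ACC and V1, 0.12 for HC and V1 and -0.03 for DLPFC and V1. Spearman's rho was 0.09 for DLPFC and ACC and -0.09 for DLPFC and V1. Genes are not independent replicates, and the regions came from the same 13 animals, so values above 0 can arise without an effect of MIA and no p is given. Among called genes, DLPFC and HC shared 1 higher gene, C15orf41, against 0.0122 for independent lists, and 1 lower gene, PIWIL2, against 0.00982. No called gene was shared between V1 and another region. Of 204 tests of a list's difference between 2 regions, 63 passed at the preset correlation of 0.01 and 4 with an estimated correlation (cameraPR on unscaled differences, Benjamini-Hochberg). The myelin list differed between DLPFC and HC by a median of -1.07 for DLPFC minus HC (adjusted p = 2.09e-37; adjusted p = 0.0850 with an estimated correlation).

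The authors' deposited module table assigned 14957 genes to 28 co-expression modules and an unassigned grey set of 6773 genes. The modules were built on these libraries, so their direction is not independent evidence. The turquoise module, the largest with 1086 genes, held 25 of 25 measured myelin genes (Fisher's exact test, two-sided, adjusted p = 2.55e-26), and its hub genes were PLEKHG3, LLGL1 and NPC1. Its median log2 fold change was 0.10 in HC (adjusted p = 1.63e-05; adjusted p = 0.219 with an estimated correlation). The lightcyan module of 188 genes, with the hub genes ITIH5, COLEC12 and FN1, held 8 of 10 meninges and fibroblast genes (Fisher's exact test, two-sided, adjusted p = 1.17e-11), with a median of 0.29 in HC (adjusted p = 6.28e-07; adjusted p = 0.834 with an estimated correlation). The steelblue module of 105 genes, with the hub genes ANXA10, INSIG2 and ALB, was lower, with a median of -0.13 in DLPFC (adjusted p = 6.61e-07; adjusted p = 0.834 with an estimated correlation), -0.12 in ACC (adjusted p = 1.15e-10; adjusted p = 0.795 with an estimated correlation) and -0.19 in HC (adjusted p = 4.85e-09; adjusted p = 0.795 with an estimated correlation). In V1 its median of -0.06 was not called (adjusted p = 0.0671). The darkgreen module of 134 genes, whose hub genes included the corepressor NCOR1, had a median of 0.22 in DLPFC (adjusted p = 1.33e-14; adjusted p = 0.667 with an estimated correlation) and -0.08 in ACC (adjusted p = 1.80e-07; adjusted p = 0.795 with an estimated correlation). The red module of 396 genes held 8 of 13 mitochondrially encoded genes (Fisher's exact test, two-sided, adjusted p = 8.48e-08). Its median was -0.11 in ACC (adjusted p = 7.73e-11, and 0.667 with an estimated correlation) and 0.11 in DLPFC (adjusted p = 0.0278, and 0.945 with an estimated correlation). In V1 darkred and darkorange were called higher (adjusted p = 0.0186 and 0.00418, and 0.882 and 0.795 with an estimated correlation). The darkorange module went the other way in DLPFC, with a median of -0.10 (adjusted p = 0.000212, and 0.720 with an estimated correlation). Among the single regions, turquoise and lightcyan were not called in DLPFC, ACC or V1, nor darkgreen or red in HC or V1. Module tests used cameraPR (limma) with the same preset correlation. Of the 132 genes called in a region, 68 were in the grey set, among them PIWIL2, MGARP and C15orf41.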

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

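All tests of explanations here were chosen after the results had been seen, as was the cerebellum list; the comparison of libraries within a group followed a fixed rule. Of 96 groups of libraries and measures checked, 13 had 1 library far from the others, where chance alone gives about 1 in 20 for unrelated groups. The groups here share libraries, and animal 39827 in DLPFC was flagged for several measures. No excess over chance is therefore read from this count. All directions rest on reading the fold changes as MIA over control, which no value settles; with the ratio turned, higher and lower swap, and so do the groups that an explanation names.

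Cerebellar genes were lower in V1 and lay below the other regions, with a median difference of 1.10 for DLPFC minus V1, 0.99 for ACC minus V1 and 1.05 for HC minus V1; a test of this on a list written from the V1 calls would repeat the choice, so no p is given. Lower RNA integrity in control V1 is not decided by these values. The integrity number was 7.60 ± 0.682 in MIA (SD, n = 9) and 7.03 ± 1.20 in control (SD, n = 4) in V1. In ACC it was 7.97 ± 0.412 in MIA (SD, n = 9) and 7.22 ± 0.695 in control (SD, n = 4). The cerebellum median in ACC was -0.018, with quartiles of -0.10 to 0.07 against -1.46 to -0.36 in V1. A gap in mean integrity in ACC thus went without the shift. This cannot decide, because the list was written from the V1 calls and the lowest control library stood at 6.0 in V1 and 6.4 in ACC. The lowest V1 library of any group was 1 of second-trimester MIA, at 5.9. More cerebellar tissue in the control than in the MIA V1 dissections may account for the pattern but stays open, because the list was written after the V1 calls had been seen. Its 23 members without a call had a median of -0.82 in V1 and medians within 0.25 of 0 in the other regions. Single members moved outside V1 as well, in both directions. In the authors' deposited table CBLN3 had -3.39 in V1 and 1.21 in HC, and GABRA6 had -2.91 in V1, -0.74 in DLPFC and -0.76 in ACC. FAT2 had -1.37 in DLPFC and 1.33 in HC. An effect of MIA on these genes in visual cortex also stays open, since 93.9% of the 33 measured members were lower either way and levels per library were not used here. Of these members, 6 are on another list.

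Myelin genes were higher in HC (adjusted p = 9.28e-16; adjusted p = 0.651 with an estimated correlation). Choroid plexus and ependyma genes in HC also lay above the other regions, by a median difference of -0.88 for DLPFC minus HC, -0.80 for ACC minus HC and 0.88 for HC minus V1 (cameraPR on unscaled differences with an estimated correlation, adjusted p = 5.63e-07, 9.86e-06 and 0.00588). These tests do not take each gene's error into account. Within HC that list was not called (cameraPR, adjusted p = 0.0970, and 0.870 with an estimated correlation). No member passed there, and none had an unadjusted p under 0.05. A lower neuron share that raises every other cell type alike is not decided by these values. The deposited medians were not alike over the lists. The myelin quartiles were 0.70 to 0.92, and 100 members of 8 other non-neuronal lists had a median of 0.24 and quartiles of 0.02 to 0.46. List medians ran from 0.00 for oligodendrocyte precursors and 0.02 for astrocytes to 0.56 for meninges and 0.75 for choroid plexus. These quartiles run over genes and not over animals, and the myelin genes had an estimated correlation of 0.91. The rule for this comparison was also worded after the values had been seen. A larger white matter share in the MIA hippocampus samples is a candidate explanation, as the synaptic vesicle median was -0.19 and the abundant myelin gene MBP was at 0.92 in the authors' deposited table without passing, but the excitatory neuron and interneuron medians were -0.03 and -0.07 (adjusted p = 0.916 and 0.899). More oligodendrocyte gene expression after MIA stays open, because 100% of the 25 members were higher under both.

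Ribosomal and oxidative phosphorylation genes were lower in DLPFC (adjusted p = 1.31e-18 and 7.76e-09; adjusted p = 0.426 and 0.570 with an estimated correlation). Oxidative phosphorylation genes went in opposite directions in DLPFC and V1. They were lower in 48 of 55 in DLPFC, with quartiles of -0.26 to -0.06, and higher in 49 of 55 in V1, with quartiles of 0.07 to 0.21. The median difference was -0.31 for DLPFC minus V1 (cameraPR on unscaled differences). Its adjusted p was 2.08e-05 at a preset correlation of 0.01, 0.0191 at 0.05 and 0.446 with an estimated correlation. The difference thus holds at the preset correlations alone. Whether 1 effect of MIA was shared by the 4 regions stays open, because the sequencing batch splits DLPFC alone and may enter this contrast. Whether the authors' fit adjusted for the sequencing batch that splits the DLPFC libraries is not known here. The batch therefore cannot be told apart from MIA without values per library. Of the DLPFC libraries, 7 of 9 MIA and 2 of 4 control were in the first batch (Fisher's exact test, two-sided, p = 0.530). A difference between exposures in DLPFC in sequencing depth (exact permutation test, two-sided, p = 0.534) or in solvent carryover (p = 0.157 for pooled MIA, n = 9 against 4, and 0.0317 for first-trimester MIA, both exact) could matter as well.

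The pericyte and smooth muscle list differed between DLPFC and ACC by a median of 0.48 (cameraPR on unscaled differences with an estimated correlation, adjusted p = 0.0287). In ACC, control animal 40482 had the highest depth of the 4 control libraries, 34.3 M, against 27.9 for the next control, and a seqPC1 of -0.104. Animal 40212 of second-trimester MIA had a solvent-carryover absorbance ratio of 2.11 in ACC. In DLPFC, animal 39827 of first-trimester MIA had an RNA integrity number of 7.4, a depth of 49.4 M and a seqPC1 of -0.318; it was the 1 animal of its group in the second batch. Animal 40318 of the same group had a seqPC2 of 0.304 in DLPFC. In HC, animal 39813 of first-trimester MIA had a solvent-carryover absorbance ratio of 2.14. In V1, control animal 40478 had a seqPC2 of -0.255 and a seqPC3 of -0.536, and animal 40360 of first-trimester MIA had -0.191 and -0.378. Animal 39827 had a protein-carryover absorbance ratio of 2.04 in V1.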

How the results depend on the processing

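Chosen after the data had been seen were the Benjamini-Hochberg adjustment within each comparison, the cerebellum list and the counts without its genes, the estimated correlation, 1 entry per gene name, the tests of differences between regions and the pooled metadata tests. No paired analysis was possible because the exposures share no animal and the fold changes came from the authors' table without values per library. Not run for the same reason were fits per library, filters on mean expression, counts without a doubted library and the agreement between trimesters. Depth per library is given, but how it limits single genes cannot be read from that table. The main counts of called genes are 14 in DLPFC, 1 in ACC, 47 in HC, 73 in V1 and 3 combined. They were 34 in DLPFC, 4 in ACC, 118 in HC, 114 in V1 and 6 combined at an FDR under 0.1, 2 in DLPFC, 0 in ACC, 8 in HC, 15 in V1 and 3 combined under 0.01, and 75 in DLPFC, 18 in ACC, 285 in HC, 195 in V1 and 106 combined at an unadjusted p under 0.005. With Benjamini-Hochberg adjustment over all comparisons together they were 0 in DLPFC, 0 in ACC, 0 in HC, 0 in V1 and 1 combined, and within each comparison 0 in DLPFC, 0 in ACC, 3 in HC, 3 in V1 and 3 combined; both replace the authors' shared adjustment. A fold change limit, genes with a symbol only and leaving out cerebellar genes kept each count within 1.5 times. The share of higher genes among those with an unadjusted p under 0.05 was 51.3% in DLPFC, 39.1% in ACC, 52.3% in HC, 27.0% in V1 and 48.9% combined; the cause was not tested. With the ratio turned, these would be shares of lower genes.

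Called lists numbered 5 in DLPFC, 0 in ACC, 2 in HC, 1 in V1 and 2 combined at a correlation of 0.05, 10 in DLPFC, 5 in ACC, 13 in HC, 7 in V1 and 7 combined by ranks, 13 in DLPFC, 4 in ACC, 11 in HC, 6 in V1 and 9 combined by log2 fold change, 8 in DLPFC, 2 in ACC, 6 in HC, 4 in V1 and 4 combined without the largest member, and 0 in DLPFC, 0 in ACC, 0 in HC, 0 in V1 and 0 combined with an estimated correlation. A larger correlation widens the test by construction; the cause of the other shifts was not tested. Of the 34 calls, 34 held by ranks, 31 with 1 entry per gene name of the file, 28 by log2 fold change, 24 without the largest member and 10 at a correlation of 0.05, and no list turned direction. With 1 entry per name, the calls that ended were microglia in DLPFC (adjusted p = 0.0509), ribosomal proteins in ACC (0.237) and perineuronal net in HC (0.0726), where fewer entries were tested. Called modules numbered 2 in DLPFC, 3 in ACC, 1 in HC, 0 in V1 and 1 combined at a correlation of 0.05, 15 in DLPFC, 7 in ACC, 19 in HC, 8 in V1 and 14 combined over members with a membership of at least 0.7, and 0 in DLPFC, 0 in ACC, 0 in HC, 0 in V1 and 0 combined with an estimated correlation. Of these module counts, 14 moved beyond 1.5 times the main count and 1 stayed within it. The 9 enrichments of lists in modules stayed within 1.5 times.

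Spearman's rho between regions was 0.0901 for DLPFC and ACC, 0.139 for DLPFC and HC, -0.0891 for DLPFC and V1, 0.163 for ACC and HC, 0.186 for ACC and V1, 0.134 for HC and V1. Over genes with an unadjusted p under 0.05 in either region, Pearson's r was 0.475 for DLPFC and ACC, 0.215 for DLPFC and HC, 0.0255 for DLPFC and V1, 0.381 for ACC and HC, 0.224 for ACC and V1, 0.159 for HC and V1, so the sign turned for DLPFC and V1; the cause was not tested. Over 24 tests, a few metadata tests at the smallest p that these group sizes allow cannot pass adjustment, so their count of 0 under the alternatives says nothing about stability. Without each animal in turn, the unadjusted p of the integrity number for first-trimester MIA against control lay between 0.0357 and 0.107 (exact permutation tests), above 0.05 without any of the 5 first-trimester animals or without control animals 40295, 40335 or 40478.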

Other observations

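The lists here were fixed before the data were examined, and the implied standard errors were computed after the results had been seen. Beyond PIWIL2, genes that restrict or silence retrotransposons were not called as a group. Their adjusted p over the 5 comparisons ran from 0.307 to 0.965 (cameraPR), and PIWIL2 was the 1 member called, in DLPFC, ACC and HC. In the authors' deposited table the antiviral deaminase gene APOBEC3C had 0.80 in DLPFC (FDR = 0.325), 0.53 in ACC (FDR = 0.658) and 0.80 in HC (FDR = 0.295), none past the threshold. Oligodendrocyte precursor genes ran from adjusted p = 0.316 to 0.898, and the erythrocyte list had 2 measured members and was not tested. DNMT1, the maintenance DNA methyltransferase, had -0.43 in V1 (FDR = 0.0959) in the authors' deposited table. The list of retrotransposon-encoded or -derived genes, which also holds genes derived from DNA transposons, ran from adjusted p = 0.446 to 0.974. PGBD5, a domesticated DNA transposase on that list, was called lower in HC at -0.51 (FDR = 0.0187) in the authors' deposited table. EPHA4, an axon guidance receptor, was also called lower in HC at -0.59 (FDR = 0.0408) in the authors' deposited table. GRIK2, a kainate receptor subunit, was called lower in V1 at -0.58 (FDR = 0.00826) in the authors' deposited table.

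Of the immune lists other than the interferon list, none was called in any comparison (cameraPR). Adjusted p ran from 0.0658 to 0.989 for antigen presentation, 0.0985 to 0.936 for complement and 0.121 to 0.754 for cytokine and NF-kB genes. In HC 17 of 23 measured entries of antigen presentation genes were higher, with a median of 0.23. With 1 entry per gene name, 11 of 16 were higher, with a median of 0.22. Of the complement entries, 17 of 20 were higher, with a median of 0.22. Adjusted p ran from 0.0865 to 0.711 for immediate early genes, 0.446 to 0.938 for heat shock genes, 0.226 to 0.989 for glucocorticoid response genes and 0.0937 to 0.989 for hypoxia genes. Neuronal lists without a call ran from 0.0865 to 0.916 for excitatory neurons, 0.228 to 0.985 for interneurons, 0.0865 to 0.898 for GABA synapses, 0.210 to 0.988 for axon guidance and 0.173 to 0.989 for immature neurons. In V1, 15 of 16 excitatory neuron genes were higher, with a median of 0.23 (adjusted p = 0.0865).

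The p-values of the authors' deposited table were spread unevenly over regions. In ACC 202 genes, 1.35%, had an unadjusted p under 0.05, where uniform p-values would give 5%, and in HC 1707 genes, 11.4%. The standard error implied by fold change and p was alike in ACC and HC, with a median ratio of 0.999 and quartiles of 0.987 to 1.01. It was larger in DLPFC than in ACC, with a median ratio of 1.17 and quartiles of 1.16 to 1.19. For ACC against V1 the median ratio was 0.872, with quartiles of 0.856 to 0.901. Ratios so alike over genes cannot serve as a separate measure of noise in each region, and their cause was not tested. The SD of log2 fold changes over genes was 0.167 in ACC and 0.282 in HC, and the cause of this difference was not tested. In ACC the deposited FDR lay below the gene's own p for 5.42% of genes.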
